A study of Homo sapiens with 8 samples.

How the data were processed

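Poly(A)-selected RNA of LY2 cells was sequenced as 8 libraries, 4 with a non-targeting hairpin (shNT) and 4 with short hairpin RNA against NCOA1 (shSRC1). Groups and replicate numbers were taken from the labels. The main test, filter, thresholds, gene lists, rule for named genes and first set of alternative settings were fixed before the data were examined. Per the labels' protocols, the cells were held under 500 ng/mL puromycin to keep the hairpins, were kept without steroids for 72 h and were treated with 4-hydroxytamoxifen for 8 h, and libraries were made with an Illumina TruSeq RNA kit from oligo(dT)-captured RNA. The labels do not describe the kit as stranded.

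The authors deposited a table of 63677 genes by 8 libraries in which each value is a signal proportional to reads, a read count divided by the size factor of its library. Per the submitters' processing notes, TopHat2 2.0.12, HTSeq 0.6.1, DESeq2 and DESeq were used with the GRCh37 build; counting options and annotation are not given in the sources used here. The column names speak of raw counts, but the deposited values are not whole. Within each library every value was a whole multiple of a fixed step, with 100.0% of values whole within 0.001 reads, and the inverse steps equalled the median-of-ratios size factors computed from the recovered reads. The table held Ensembl gene identifiers, with a symbol for 37222 genes and none for 26455. A read was seen in at least 1 library for 38332 genes. The recovered depth was 63804191, 67022036, 58459196 and 65751891 reads for shNT replicates 1 to 4 and 65352354, 33771775, 65321247 and 66248960 for shSRC1 replicates 1 to 4. A value of 3 reads, the floor used for a count of 0, corresponds to 2.67 to 2.79 normalized reads in the shNT libraries and to 2.73 to 5.25 in the shSRC1 libraries. Counting intervals and floors cover counting error only, and may be too narrow for it, since reads without molecular identifiers are not independent molecules. Confidence intervals of log2 fold changes come from limma and measure the spread between libraries.

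Because the values are not counts, the main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend and robust variances on log2(value + 1), the test fixed for normalized values. Fold changes are on that log2(value + 1) scale, which understates the change of genes with low values. Genes with at least 10 normalized reads in at least 4 libraries were tested, 19559 in all. P-values are two-sided and Benjamini-Hochberg adjusted over these genes, with a threshold of 0.05, and no replicate block was used. The 31 gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 31 lists. Members were also counted with p-values adjusted over the list alone. The lists cover nuclear receptor coregulators, genes linked to SRC-1, estrogen receptor targets, breast lineage, adhesion and matrix, cell cycle, p53, interferon, inflammation, growth factor signalling, lipid and glucose metabolism, stress responses, TGF-beta, Notch and Wnt, chromatin enzymes, neuronal and axon guidance genes, mammary differentiation, other cell types, ribosomal proteins, mitochondrial transcripts and histones. The fibroblast, leukocyte, ribosomal, mitochondrial and histone lists were included to look for other cell types and for differences in RNA quality and library preparation. Of 688 list entries, 683 were matched by the symbol in the table, 4 through another symbol of the same gene, and 1 was not matched.

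The genes named by rule were NCOA1, NCOA2 and NCOA3, the 10 largest rises and 10 largest falls among genes with a symbol, an adjusted p under 0.05, a mean of at least 50 normalized reads in the higher group and groups that did not overlap, and up to 4 members of each list past the threshold, by smallest adjusted p. Other genes in the text were chosen after their values were seen, namely GREB1, PGR, TFF1, ESR1, TBL1XR1, the interferon genes named for their position, LYZ, and the NRF2 and cancer-testis genes among the other observations. Some genes that the rule takes are not reported here.

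The reference annotation was GENCODE 29 on GRCh38, a different build from that of the table, so it was used only for gene order, chromosome numbers and transcript length and GC content, joined by Ensembl identifier, and no coordinates are given. Length and GC content of the longest transcript were found for 18787 of the 19559 tested genes, or 96.1%. Running medians over 100 neighbouring protein-coding genes were compared with 1000 shuffles of gene order, and a run was kept if it held at least 100 genes. The search and its minimum size were chosen after fold changes had been seen, the minimum because shorter fragments were numerous without it.

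The alternatives fixed at the outset were edgeR 4.0.16 TMM and upper-quartile scaling, no filter and a minimum of 50, pseudocounts of 0.5 and 5, a replicate block, each library left out in turn, and edgeR's quasi-likelihood test, DESeq2 1.42.0 and limma-voom on the recovered reads. On the recovered reads edgeR called 4637 genes. A further 4 settings were added after seeing the data, namely leaving out shNT replicate 3 and shSRC1 replicate 2 together, thinning all libraries to the smallest depth, correcting each library for its trend with transcript length and GC content by natural splines, and leaving out the genes of the chromosome runs. Replicates were compared before averaging, and in the 12 pairs within groups a chi-square of the reads over genes was 6.04 to 77.6 per degree of freedom, so no pair was alike within sampling noise.

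The tests were tried on simulated data first. For the comparison of shSRC1 with shNT, counts of 19559 genes were drawn from the real means, dispersions and depths with 200 changed genes. Of the changed genes limma found 51.8% at 1.5-fold, 65.8% at 2-fold and 94.4% at 4-fold, and 10 of its 154 calls, or 6.49%, were false, above the 5% that the threshold aims at. In the same simulation 15.6% of the calls were false for DESeq2, 4.61% for edgeR and 5.88% for limma-voom. The simulation was run once and drew genes independently, with far fewer changed genes than the 4538 called in the real data. These rates may therefore not hold for the real data. Summaries, shuffles and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.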

Results

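RNA was profiled in LY2 cells, an endocrine-resistant variant of the MCF-7 breast cancer line, that stably carried either a non-targeting short hairpin RNA (shNT) or short hairpin RNA against NCOA1 (shSRC1). NCOA1 encodes SRC-1, a coactivator of the estrogen receptor and other nuclear receptors. All cells were kept without steroids for 72 h and then received 4-hydroxytamoxifen, the active tamoxifen metabolite, for 8 h. Each group held 4 libraries. The deposited values were size-factor normalized read counts per gene, from which whole reads could be recovered. The shNT libraries held 58459196 to 67022036 reads assigned to genes, and shSRC1 replicates 1, 3 and 4 held 65352354, 65321247 and 66248960. The library of shSRC1 replicate 2 held 33771775. Nothing in the labels says that the replicates came from separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

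The comparison of shSRC1 with shNT asks which genes respond to lower SRC-1 in tamoxifen-treated resistant cells. NCOA1 (ENSG00000084676) itself fell from 4396 ± 137 to 2036 ± 151 normalized reads (mean ± SD, n = 4 per group). Its log2 fold change was -1.11 (SE 0.08, 95% confidence interval -1.28 to -0.94), with an adjusted p of 2.25e-07 in limma. The 4 shNT libraries held 4381, 4212, 4467 and 4525 normalized reads and the 4 shSRC1 libraries 1927, 1895, 2215 and 2107, so the groups did not overlap. An exact two-sided permutation test of these values gave p = 0.0286, the smallest that 4 against 4 libraries allow. NCOA2, which encodes the related coactivator SRC-2, stood at 3681 ± 217 in shNT and 3598 ± 242 in shSRC1 (n = 4 each), a log2 fold change of -0.03 (SE 0.08, limma adjusted p = 0.793). NCOA3, which encodes SRC-3, stood at 78065 ± 2351 and 66131 ± 4094 (n = 4 each), a log2 fold change of -0.24 (SE 0.09) that missed the threshold (limma adjusted p = 0.0548). Over 21 alternative settings its adjusted p ran from 0.0035 to 0.175, and it passed the threshold in 10 of them, among them both other scalings.

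**Figure D1:**
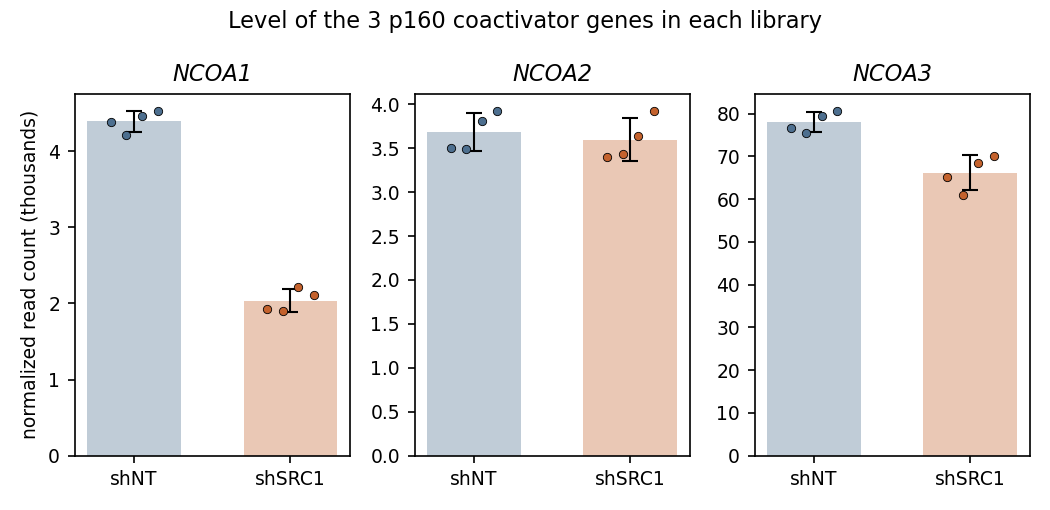
Normalized read counts, divided by 1000 on the y axis, of NCOA1, NCOA2 and NCOA3 in the shNT and shSRC1 libraries. Points are libraries, bars are group means and error bars are SDs (n = 4); NCOA1 lies at 4212 to 4525 normalized reads in shNT and at 1895 to 2215 in shSRC1.

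Beyond NCOA1, the largest rises were in genes with low values in shNT cells, from 1.37 normalized reads for VCAM1 to 77.5 for FCGR2B. NTRK2, which encodes the neurotrophin receptor TrkB, rose from 63.6 ± 5.4 to 1798 ± 169 normalized reads (n = 4 each), a log2 fold change of 4.80 (SE 0.11, limma adjusted p = 1.34e-12). VCAM1, a cell adhesion receptor bound by leukocyte integrins, rose from 1.37 ± 1.16 to 66.7 ± 7.6, on 6 reads in all shNT libraries together and 250 in the shSRC1 libraries. The synaptic adhesion gene CLSTN2, the potassium channel gene KCNJ8, the transcriptional coregulator gene CITED1, the branched-chain amino acid transaminase gene BCAT1 and IGFL1 rose by log2 fold changes of 4.51, 4.37, 3.84, 3.44 and 3.22. The Fc receptor genes FCGR2B and FCGR2C rose by 3.22 and 3.20 in the same order. FCGR2B and FCGR2C are near-identical copies that can share reads, so their separate values are uncertain. The limma adjusted p-values of these genes lay between 1.34e-12 and 0.0012.

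Among the largest falls, SSX2, a cancer-testis antigen gene, fell from 323 ± 25 to 3.19 ± 0.54 normalized reads (n = 4 each), a log2 fold change of -6.28 (SE 0.22, limma adjusted p = 2.13e-10). Its copy SSX2B, which can share reads with it, fell by 5.57 on the log2 scale, and the germline gene TDRD1 by 5.79. ACN9, which encodes a succinate dehydrogenase assembly factor, had 254 reads in the shNT libraries and 0 in the shSRC1 libraries, at least 73.3-fold lower against a floor of 3 reads over the group. TM4SF5 had 264 reads in shNT and 1 in shSRC1, a ratio of 229 with an exact 95% counting interval of 40.8 to 9089. AKR1C2, which encodes an aldo-keto reductase that inactivates androgens, fell from 7538 ± 1202 to 931 ± 91, a log2 fold change of -3.01 (SE 0.11, limma adjusted p = 3.70e-10). AKR1C2 can share reads with AKR1C1 and AKR1C3. ACN9 lies in a run of lower genes on chromosome 7, TDRD1 and AKR1C2 lie in such runs on chromosome 10, and TM4SF5 lies in a run of higher genes on chromosome 17. ITM2A, the amino acid transporter gene SLC6A14, the ribosomal pseudogene RPL7P4 and the antisense transcript RFPL1S had log2 fold changes of -4.02, -2.87, -5.34 and -3.24. The last 2 are uncertain, because RPL7P4 copies a ribosomal protein gene and no source used here says that counting used strand.

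**Figure D2:**
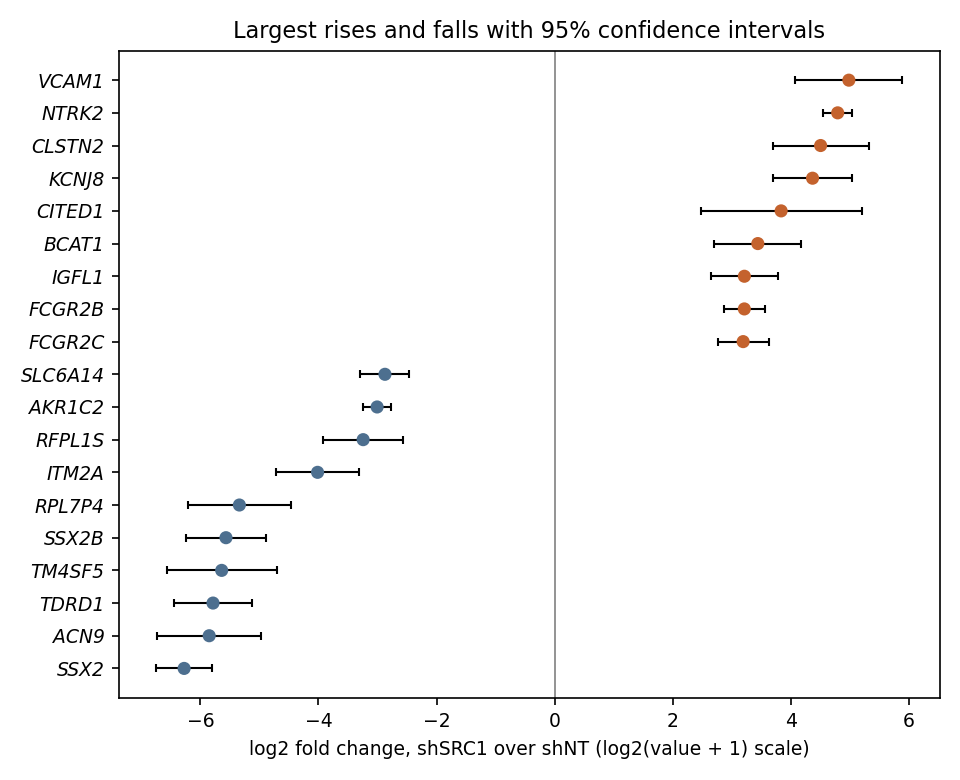
Log2 fold change of shSRC1 over shNT on the x axis for the genes named in the text among the 10 with the largest rise and the 10 with the largest fall, with 95% confidence intervals as error bars. The values run from -6.28 for SSX2 to 4.99 for VCAM1; that of ACN9, with 0 reads in shSRC1, depends on the pseudocount of 1 and is no bound.

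In all, 4538 of 19559 tested genes passed an adjusted p of 0.05 in limma, 2344 higher and 2194 lower in shSRC1. At least a 2-fold change on the log2(value + 1) scale was seen in 693 of these genes. The groups did not overlap in 5667 genes, or 28.97% of those tested, where chance gives 2.86%. Without shSRC1 replicate 2, the library with the fewest reads, 1453 genes were lower in place of 2194. With a minimum of 50 in place of 10 normalized reads, 348 genes changed at least 2-fold. The 4538 calls are 23.2% of the tested genes. A gene list with about this share of its members called, or less, does not stand out by that count.

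Of 35 measured estrogen receptor target genes, 15 rose, 3 fell and 17 did not pass the test, and 16 rose and 4 fell adjusted over the list alone. KRT13, a keratin gene, rose from 3511 ± 514 to 13876 ± 572 normalized reads (n = 4 each), a log2 fold change of 1.99 (SE 0.10, limma adjusted p = 6.98e-09). The apoptosis inhibitor BCL2 rose from 421 ± 46 to 1282 ± 89, PDZK1 from 374 ± 12 to 1152 ± 164 and the secreted glycoprotein gene STC2 from 12374 ± 905 to 28825 ± 1233. BCL2 lies on chromosome 18, where neighbouring genes were also higher. The receptor tyrosine kinase RET fell from 6728 ± 341 to 4037 ± 165, and lies in a run of lower genes on chromosome 10. The classical targets GREB1, PGR and TFF1 had log2 fold changes of 0.02, 0.35 and 0.14 with limma adjusted p-values of 0.893, 0.298 and 0.543. The list as a whole was higher in camera (adjusted p = 9.56e-04 over 31 lists), though not with an estimated correlation (adjusted p = 0.744).

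Markers of luminal breast identity went both ways, with 6 of 18 measured rising and 3 falling, the same counts adjusted over the list alone. KRT8 and KRT19, keratins of luminal epithelium, rose by log2 fold changes of 0.68 (SE 0.12) and 0.68 (SE 0.11), and the secreted disulfide isomerases AGR2 and AGR3 by 0.82 and 2.02. In shNT replicate 3, KRT8 and KRT19 stood at 103828 and 46192 normalized reads, against at least 137714 and 61703 in the other shNT libraries. ESR1, which encodes the estrogen receptor, stood at 20472 ± 349 in shNT and 18728 ± 946 in shSRC1 (n = 4 each, limma adjusted p = 0.233). Of 13 measured basal and myoepithelial markers, 5 fell and 1 rose, the same adjusted over the list alone. Of these 6 calls, 2 were kept without shNT replicate 1 and 3 without shSRC1 replicate 4. KRT16 fell by 1.25 (SE 0.30) on the log2 scale, and TP63 rose by 1.05 (SE 0.18).

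Interferon response genes were lower in shSRC1. Of 27 measured, 16 fell, none rose and 11 did not pass the test, and 18 fell adjusted over the list alone. Of the 16 calls, 9 were kept without shSRC1 replicate 1, 10 without shNT replicate 2 and 10 without shNT replicate 4. Relative to the mean of all libraries, the list's median stood at -0.073 on the log2 scale in shNT replicate 1 and between 0.38 and 0.46 in the other shNT libraries, and at -0.067 in shSRC1 replicate 3 and between -0.59 and -0.17 in the other shSRC1 libraries, so the groups overlapped. IFI27 fell from 4713 ± 1099 to 705 ± 91 normalized reads (n = 4 each), a log2 fold change of -2.72 (SE 0.15, limma adjusted p = 1.08e-07). The antiviral sensors and effectors OAS3, IFIH1 and OAS1 fell by 0.69, 0.77 and 1.03 on the log2 scale. The median of the list was -0.65, and camera placed it below the other genes (adjusted p = 1.83e-08), though not with an estimated correlation (adjusted p = 0.744). Of the 27 genes, 5 lie in chromosome runs of shifted genes, among them IFIT1, IFIT2, IFIT3 and XAF1. Of 13 measured NF-kB and inflammatory genes, 3 fell and 1 rose, the same adjusted over the list alone. BIRC3, an inhibitor of apoptosis, fell by 1.70 (SE 0.28) and NFKB2, in a run of lower genes on chromosome 10, by 0.58 (SE 0.10).

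Of 22 AP-1 and immediate early genes, 5 fell and 1 rose, the same adjusted over the list alone. FOSL1 fell from 396 ± 21 to 196 ± 34 normalized reads (n = 4 each, limma adjusted p = 9.67e-05), and FOSB, NR4A1 and EGR1 had log2 fold changes of -1.08, -0.80 and -0.75. Of 15 measured MAPK feedback genes, 6 fell and 3 rose, and 8 fell and 4 rose adjusted over the list alone. The receptor gene EPHA4 fell by 0.92 (SE 0.09) and the phosphatase gene DUSP4 by 0.64 on the log2 scale, while PHLDA1 and cyclin D1 (CCND1) rose by 0.78 and 0.45. Of 22 measured receptor tyrosine kinase and ERBB genes, 7 fell and 4 rose, and 8 fell and 4 rose adjusted over the list alone. The insulin receptor substrates IRS1 and IRS2 fell by 0.54 and 0.62, and the EGFR ligand gene AREG rose by 0.74. IRS2 lies in a run of lower genes on chromosome 13.

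Target genes of p53 were higher in shSRC1. Of 24 measured, 13 rose and none fell, and 16 rose adjusted over the list alone. BTG2, an antiproliferative factor, rose from 1187 ± 106 to 2139 ± 125 normalized reads (n = 4 each), a log2 fold change of 0.85 (SE 0.09, limma adjusted p = 1.33e-05). The stress sensor SESN2 rose by 0.69, the cyclin-dependent kinase inhibitor CDKN1A by 0.60 and the receptor gene EDA2R by 0.67. The list median was 0.33 and camera placed it above the other genes (adjusted p = 3.95e-05), though not with an estimated correlation (adjusted p = 0.744). Of 24 genes of the unfolded protein and amino acid stress responses, 11 rose, 2 fell and 11 did not pass the test, and 14 rose and 3 fell adjusted over the list alone. DDIT4, an inhibitor of mTORC1, rose from 879 ± 167 to 2726 ± 343, a log2 fold change of 1.64 (SE 0.13), although it lies in a run of lower genes on chromosome 10. The serine synthesis gene PSAT1 rose by 0.61, while SLC7A11, the cystine transporter, fell from 8196 ± 928 to 3558 ± 382 (log2 fold change -1.20, SE 0.10, limma adjusted p = 1.28e-06). Camera gave an adjusted p of 0.0028 for this list, which was lost with an estimated correlation (adjusted p = 0.744).

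Of 25 mitosis and G2/M genes, 5 rose and 2 fell, the same adjusted over the list alone. AURKB and CDC20 rose by log2 fold changes of 0.43 and 0.46, and MKI67 and KIF11 fell by 0.59 and 0.65. AURKB lies in a run of higher genes on chromosome 17 and MKI67 and KIF11 in runs of lower genes on chromosome 10. Of 27 DNA replication genes only TYMS passed the test, over all genes or adjusted over the list alone, and rose by 0.40 (SE 0.08). TYMS lies among the higher genes of chromosome 18. For hypoxia and glycolysis, 2 of 22 measured genes rose (PGK1 by 0.47 and EGLN3 by 0.47) and BNIP3, in a run of lower genes on chromosome 10, fell by 0.44, the same adjusted over the list alone. For cholesterol synthesis, 3 of 25 rose, among them INSIG1 by 0.44 (SE 0.09), and 1 fell, the same adjusted over the list alone. For lipid droplets and fatty acids, 4 of 22 rose and 5 fell, and 5 rose and 6 fell adjusted over the list alone. Among them the lipogenic regulator SREBF1, in a run of higher genes on chromosome 17, rose by 0.51, PPARGC1A by 0.68 and FABP5 by 0.43, and the acyl-CoA synthetase ACSL3 fell by 0.52.

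Ribosomal protein genes were higher in shSRC1. Of 28, 26 rose and none fell, and 27 rose adjusted over the list alone. Without shSRC1 replicate 1, 17 of the 26 calls were kept. The median log2 fold change was 0.49. RPSA rose from 10597 ± 1835 to 16820 ± 1858 normalized reads (n = 4 each), a log2 fold change of 0.68 (SE 0.12, limma adjusted p = 0.0014), and RPL11, RPL7A and RPL14 rose by 0.58, 0.53 and 0.53. Camera placed the list above the other genes (adjusted p = 4.07e-10), though not with an estimated correlation (adjusted p = 0.744). Fry, which tests a list against no change and not against the other genes, gave an adjusted p of 0.0570. Reads of these genes can be shared with their many pseudogenes. Relative to the mean of all libraries, the list's median stood at -0.69 on the log2 scale in shNT replicate 3 and between -0.19 and -0.02 in the other shNT libraries. Without that library the list median was 0.34. Libraries also differed in how their values followed transcript length and GC content: across genes, Spearman's rho with GC content ran from -0.22 in shSRC1 replicate 4 to 0.48 in shSRC1 replicate 1, though genes are not independent replicates.

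Of 13 mitochondrially encoded genes, 2 fell and none rose, the same adjusted over the list alone, MT-CO1 by 0.43 (SE 0.11) and MT-ND1 by 0.38 (SE 0.12) on the log2 scale. The fall of MT-ND1 was lost without shNT replicates 1 or 3 or shSRC1 replicates 2, 3 or 4, with limma adjusted p-values of 0.111, 0.0752, 0.0903, 0.0916 and 0.0840. The mitochondrial share of reads was 6.84% ± 0.92 in shNT and 5.46% ± 0.30 in shSRC1 (SD, n = 4 each). Camera gave an adjusted p of 0.0236, and 0.744 with an estimated correlation. The camera call was lost without shNT replicate 1 (adjusted p = 0.137), without shSRC1 replicates 2, 3 or 4 (adjusted p = 0.0521, 0.120 and 0.0804) and with each library corrected for transcript length and GC content (adjusted p = 0.0936). Of 13 measured replication-dependent histone genes, 4 rose and none fell, and 8 rose and 1 fell adjusted over the list alone. HIST1H4H, HIST1H1C and HIST3H2A rose by log2 fold changes of 0.60, 0.57 and 0.71, and HIST2H2AA3, which has a near-identical copy, by 0.48. Camera gave an adjusted p of 0.0224 for the histones, and 0.744 with an estimated correlation. The camera value was 0.0609 without shNT replicate 3 and 0.114 without shNT replicate 3 and shSRC1 replicate 2 together, where HIST2H2AA3 rose by 0.26.

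**Figure D3:**
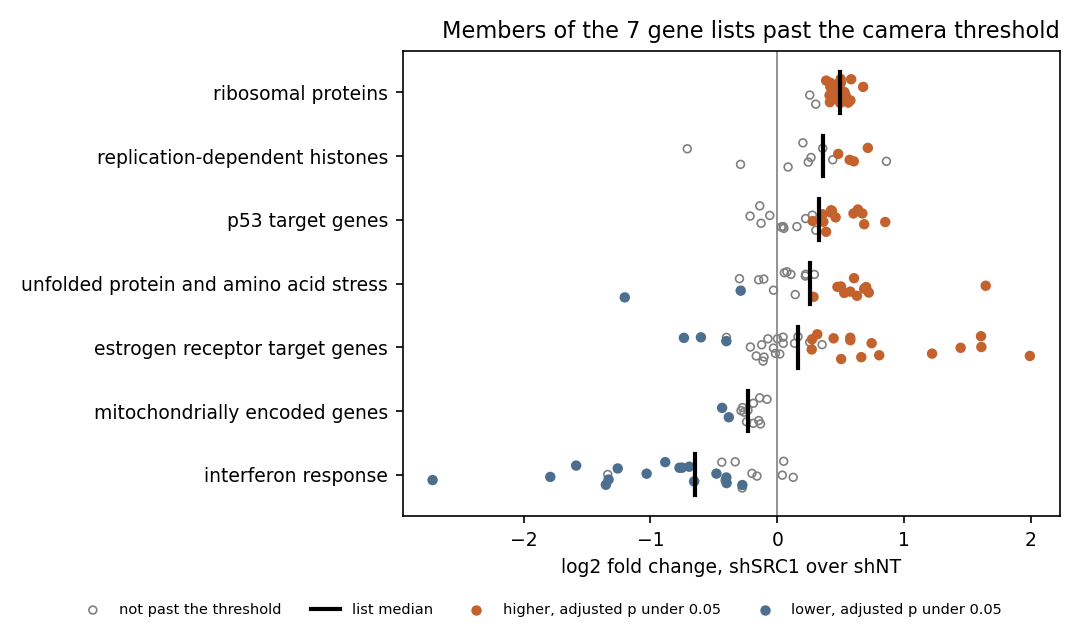
Log2 fold change of shSRC1 over shNT on the x axis for each measured member of the 7 gene lists past the camera threshold with a preset correlation. Filled points passed an adjusted p of 0.05 (orange higher, blue lower), open points did not, and black bars are list medians, from -0.65 for interferon response to 0.49 for ribosomal proteins.

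Of 24 measured integrins and matrix proteases, 8 fell and 5 rose, and 9 fell and 6 rose adjusted over the list alone. The protease genes ADAMTS1 and MMP16 had log2 fold changes of -1.56 (SE 0.18) and 1.51 (SE 0.12), the urokinase receptor PLAUR fell by 1.21 and TIMP3 rose by 0.65. Of 22 epithelial adhesion genes, 3 rose, among them OVOL2 by 0.51 (SE 0.14), and the desmosomal gene DSP fell by 0.41 (SE 0.09), the same adjusted over the list alone. Without shSRC1 replicate 1, 2 of these 4 calls were kept. Of 12 measured mesenchymal genes, FN1 and WNT5B rose by 0.78 and 1.25 and 1 gene fell, the same adjusted over the list alone. Of 21 measured TGF-beta targets, 8 rose and 2 fell, and 9 rose and 3 fell adjusted over the list alone, with ID1, ID2, TGFB1 and TGFB2 rising by 0.77, 0.56, 0.58 and 0.55. The camera adjusted p of this list was 0.175 and ran from 0.0124 to 0.744 over its alternatives; it passed the threshold with no filter on low values (0.0124). Of 24 measured Notch and Wnt genes, 3 rose and 4 fell, and 4 rose and 4 fell adjusted over the list alone. Of the 7 calls, 4 were kept without shNT replicate 1 and 4 without shSRC1 replicate 4. The Wnt feedback genes AXIN2, RNF43 and SP5 rose by 1.99 (SE 0.29), 0.52 and 0.83, and the Notch target HEY2 fell by 0.55. Of 7 measured mammary and milk genes, WFDC2 and MUCL1 rose by 0.91 and 0.58 and the alveolar regulator ELF5 fell by 0.53. Adjusted over the list alone, 3 rose and 1 fell.

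Of 13 measured neuronal and neurotrophin genes, NTRK2 and MAP2 rose, by 4.80 and 0.39, and 3 fell, among them the adhesion gene L1CAM by 0.74 (SE 0.11), the same adjusted over the list alone. Of these 5 calls, 3 were kept without shSRC1 replicate 1 and 3 without shSRC1 replicate 2. Of 24 measured axon guidance genes, 7 rose and 6 fell, and 7 rose and 9 fell adjusted over the list alone. UNC5B and SLIT2 rose by 0.73 and 0.68 and NRP1 fell by 0.45. UNC5B and NRP1 are 2 of 13 members of this list in chromosome runs of shifted genes. Both lie in a run of lower genes on chromosome 10, although UNC5B rose. Of 28 DNA methylation and chromatin enzymes, 4 rose and 3 fell, the same adjusted over the list alone. Of these 7 calls, 3 were kept without shSRC1 replicate 1, 3 without shSRC1 replicate 2, 4 without shNT replicate 1 and 4 without shNT replicate 4. The methyl-CpG binding genes MBD1 and MBD2, both on chromosome 18, rose by 0.45 and 0.52, and TET1, in a run of lower genes on chromosome 10, fell by 0.67 (SE 0.16). Of 16 nuclear receptor coregulators, KAT2A and TBL1X rose by 0.36 and 0.31 and 3 fell, among them NCOA1 and TBL1XR1. Adjusted over the list alone, 3 rose and 4 fell. Of 6 measured genes linked to SRC-1 in earlier breast cancer work, CXCL12 and MMP9 rose by 0.58 and 0.64 and none fell, the same adjusted over the list alone. The rise of MMP9 was lost without shNT replicate 1 or shSRC1 replicates 1 or 4 (limma adjusted p = 0.053, 0.0789 and 0.060). CXCL12 lies in a run of lower genes on chromosome 10. For the 24 lists that camera did not call, its adjusted p-values lay between 0.175 and 0.958. The median and the mean log2 fold change had opposite signs for the luminal, mesenchymal, mitosis, AP-1, lipid, and Notch and Wnt lists.

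Among markers of other cell types, of 7 measured fibroblast and stromal markers, COL5A1 fell by 0.68 (SE 0.15, limma adjusted p = 0.0055) and the others did not pass the test, and adjusted over the list alone the count was also 1. Among 6 measured leukocyte and endothelial markers none passed it over all genes or adjusted over the list alone, and LYZ stood at 28.3 and 23.4 normalized reads in shNT and shSRC1 (limma adjusted p = 0.577).

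Part of the change followed position in the genome. With 13920 protein-coding genes in the order of GENCODE 29 on the GRCh38 assembly, the running median over 100 genes reached 0.47 on chromosome 18 and -0.29 on chromosome 12, while 1000 shuffles of gene order stayed between -0.17 and 0.20. In 9 runs of at least 100 genes the median lay past the 95% limits of the shuffles. All 183 genes of chromosome 18 formed a higher run with a median of 0.30, of which 94 rose and 5 fell. The higher run on chromosome 17, from RPH3AL to KCNJ12, held 252 genes with a median of 0.32. On chromosome 10 the lower runs held 365 and 155 genes with medians of -0.20 and -0.20. Further runs were lower on chromosomes 2, 7, 12 and 13 and higher on chromosome 3. In the run on chromosome 2 the median of shSRC1 replicate 4, at 0.055 relative to the mean of all libraries, lay within the range of the shNT libraries, 0.026 to 0.119. Of the 4538 called genes, 716 lay in these runs, or 15.8%, against 8.7% of the tested genes. The tested genes include some with no place in this gene order, which could not lie in a run. Within the runs 42.1% of genes were called, against 23.9% of the other ordered genes. The runs were chosen by these same fold changes, so higher shares of calls in them follow at least in part from that choice. With the 1701 tested genes of these runs left out and the fit and adjustment repeated, 3574 genes passed the threshold, 1905 higher and 1669 lower.

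**Figure D4:**
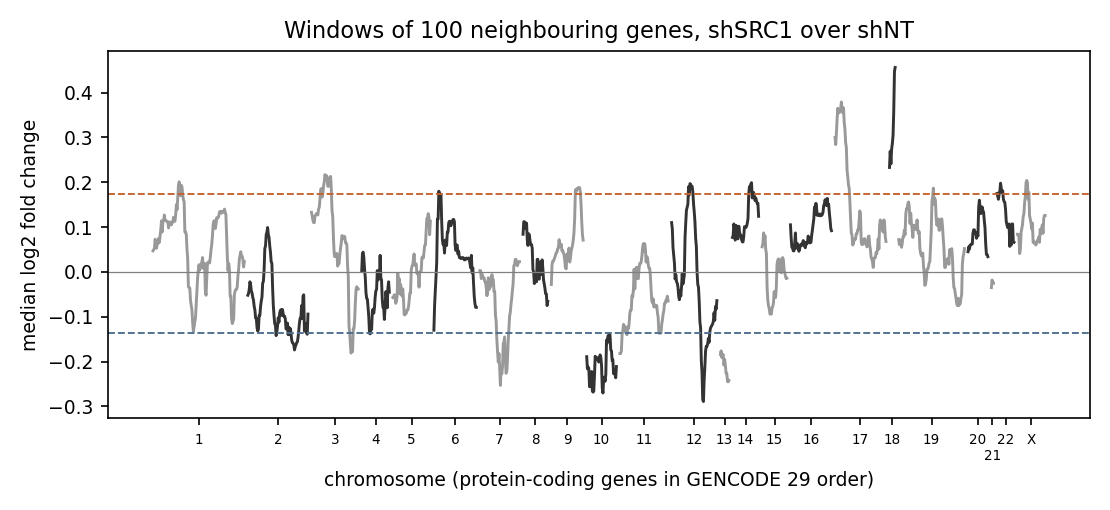
Running median of the log2 fold change of shSRC1 over shNT (y axis) over windows of 100 neighbouring protein-coding genes in the order of GENCODE 29, by chromosome (x axis). Dashed lines are the 95% limits of 1000 shuffles of gene order, 0.17 and -0.14; the windows of chromosomes 10 and 13 lie below 0 and those of chromosome 18 reach 0.47.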

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

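The tests of a single library standing apart, of chance gene order, of copy number and of other splits of the libraries were chosen only after the result they bear on was seen. Of the groups of 4 libraries examined for a single distant library, 257 in all, 16 held one (6.2%), where chance gives about 5%. In all 16 the distant library was shNT replicate 3, shSRC1 replicate 1 or shSRC1 replicate 2. Genes of 1 library are not independent, so the overall rate does not show that no library stands apart. The measure was the gap to the nearest library divided by the range of the group, with a critical ratio of 0.829.

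Ribosomal protein genes were higher in shSRC1, with a median log2 fold change of 0.49 over 28 genes. After each library was corrected for its trends with transcript length and GC content, Spearman's rho with GC content lay between -0.03 and 0.03. With length it ran from -0.17 to 0.11 before the correction and still from -0.08 to 0.05 after. In shSRC1 replicates 3 and 4 the rho with length moved from -0.02 and -0.01 to -0.07 and -0.08. After the correction shSRC1 replicates 1 to 4 stood at -0.06, 0.02, -0.07 and -0.08. The shNT replicates 1 to 4 stood at 0.05, -0.02, 0.05 and -0.01. The remaining length trend thus goes with the groups except in shSRC1 replicate 2, and is not addressed by this fit. The median after the correction was 0.45, which argues against the part of those trends that was removed as the whole cause. Without shNT replicate 3, the library where these genes were lowest, it was 0.34 with all 26 calls kept. This 0.34 lay between the bounds of 0.25 and 0.40 stated for that test, and the reading that it argues only against this library as the whole cause was adopted after the value was seen. Without shSRC1 replicate 1 the median was 0.48 and 17 of the 26 calls were kept. Reads shared with ribosomal pseudogenes were not tested, and the list was not past the threshold with an estimated correlation (adjusted p = 0.744). In shNT replicate 3, 32239 genes had a read and 7.88% of reads were mitochondrial. In the other shNT libraries these values were 29060 to 30651 and 5.91% to 7.33%. A difference in RNA quality or library preparation, which this list was included to show, was not tested and stays open. An effect of lower SRC-1 on ribosomal protein transcripts also stays open as a hypothesis.

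Interferon response genes were lower in shSRC1, with a median of -0.65 over 27 genes. After the length and GC correction it was -0.56, which argues against the part of those trends that was removed as the whole cause. Leaving out 1 library at a time gave medians from -0.76 to -0.47, the latter without shNT replicate 2, with 9 of the 16 calls kept without shSRC1 replicate 1, 10 without shNT replicate 2, 10 without shNT replicate 4, and a highest camera adjusted p of 2.31e-06, and the members outside the shifted chromosome runs had a median of -0.46. Both -0.47 and -0.46 lay between the stated bounds of -0.33 and -0.50, so they argue only against 1 library or the runs as the whole cause, a reading adopted after the values were seen. A lower interferon tone with lower SRC-1 may account for the pattern but remains a hypothesis. The list was not past the camera threshold with an estimated correlation (adjusted p = 0.744). Other differences between the shNT and shSRC1 lines are not separated from lower SRC-1 by this design.

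In 9 runs neighbouring genes were shifted together, and the furthest window lay on chromosome 18, where the median of 183 genes was 0.30. In 0 of 1000 shuffles of gene order was a 100-gene window as far from 0 (permutation p = 0.001, the smallest that these shuffles can give), which argues against chance order. After the length and GC correction the median on chromosome 18 was 0.34, which argues against the part of those trends that was removed as the whole cause there. In the other runs the median moved nearer to 0, the most on chromosome 2, from -0.168 to -0.104, and on chromosomes 12 and 13 from -0.166 to -0.119 and from -0.221 to -0.161, so a part played by those trends stays open in these runs. A DNA copy number difference between the 2 lines predicts that most genes of the run are higher at every expression level, and 79.3% and 76.9% of its genes lay above the median of all other genes among the less and the more highly expressed of them. The smaller share passed the stated bound of 75% by less than its binomial SE of 4.4 points. That margin was added after the value was seen. The run was also chosen for its high median, which by itself makes a large share likely. A copy number difference and regulation of these genes therefore cannot be told apart from RNA alone. The labels do not say whether 1 hairpin against NCOA1 or several were used, so effects of SRC-1 and differences between the selected lines are not separated by this design.

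All 35 splits of the 8 libraries into 4 and 4 were tested with limma. Only the real split, 1 of 35, gave as many as 4538 genes, and the highest of the other splits gave 0. Each other split mixes shNT and shSRC1 libraries, so a difference between the groups adds to its spread and lowers its count. Rank 1 of 35 is the most extreme that this test can give, so the test by itself cannot exclude chance as the source of the count. At an unadjusted p under 0.05 the real split gave 7352 genes and the highest other split 2446.

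In shNT replicate 3, KRT19 stood at 46192 normalized reads against 61703 to 62737 in the other shNT libraries (ratio 0.938), KRT8 at 103828 against 137714 to 144690 (0.829 when rounded, and above the critical ratio before rounding), CDC20 at 5334 against 6836 to 7081 (0.860), BTG2 at 1029 against 1219 to 1257 (0.833) and HEY2 at 292.4 against 350.1 to 355.2 (0.918). In shSRC1 replicate 1, KRT19 stood at 101251 against 88481 to 89768 (0.899), KRT8 at 235045 against 200794 to 204308 (0.897), CLDN7 at 14401 against 12313 to 12646 (0.841), CDC20 at 10328 against 8329 to 8647 (0.841) and MT-ND1 at 95168 against 78042 to 80693 (0.845). Its mitochondrial share of reads was 5.90% against 5.28% to 5.37% (0.857), and it held the single TM4SF5 read of the group (1.000). In shSRC1 replicate 2, MKI67 stood at 16591 against 18820 to 19265 (0.834), PSAT1 at 3634 against 3831 to 3861 (0.868) and HIST2H2AA3 at 1886 against 1402 to 1471 (0.858), and its depth was 33771775 reads against 65321247 to 66248960 (0.971). CLDN7, in the run of higher genes on chromosome 17, rose by 0.35 in shSRC1, and that call was lost without shSRC1 replicate 1 (limma adjusted p = 0.0643).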

How the results depend on the processing

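The fits without shNT replicate 3 and shSRC1 replicate 2 together, with thinned libraries, with the length and GC correction and without the genes of the shifted chromosome runs were chosen only after the data were seen. Across 22 alternatives the count of changed genes stayed within 1.5 times 4538, from 3166 without shSRC1 replicate 2 to 6398 with the replicate block, and with 1 library left out at least 3074 of the 4538 genes were called again. Lower genes numbered 1453 to 2291 with 1 library left out, against 2194; the lowest was without shSRC1 replicate 2 and the cause was not tested, though fewer samples enter each of these fits. Genes changed at least 2-fold numbered 348 in place of 693 with the stricter filter, which tests 15236 in place of 19559 genes. NCOA1 fell under every alternative run, with log2 fold changes of -1.15 to -1.07. NCOA2, not past the threshold, changed sign to 0.0067 (adjusted p = 0.967) without shNT replicate 3 and shSRC1 replicate 2, and the cause was not tested. Of 125 other named genes, 109 kept direction and side of the threshold under all alternatives run for them; 14 lost a call in 59 combinations of gene and setting, 42 of them with 1 library left out, and NCOA3 gained one in 10. Camera called 7 lists with the preset correlation of 0.01 and 0 with an estimated one. The estimate was 0.94 for the ribosomal, 0.74 for the mitochondrial, 0.60 for the histone and 0.51 for the stress list. It was 0.43 for interferon response, 0.26 for p53 targets and 0.12 for estrogen receptor targets. The preset thus takes members to be more independent than they were in these libraries, and its p-values for these lists may be too small. The estimated setting also lowers the degrees of freedom of the test from the number of genes to that of the libraries. The part played by each difference was not separated. With the estimated correlation 0 lists also passed an unadjusted 0.05, the smallest camera p being 0.0925. The TGF-beta list gained a camera call with no filter on low values (adjusted p = 0.0124), where more genes are tested. Fry, which tests a list against no change and not against the other genes, called 10, of which 3 were shared. The shared lists were estrogen receptor targets, p53 targets and interferon response (fry adjusted p = 0.0026, 0.0098 and 0.0217). Fry did not call the stress, ribosomal, mitochondrial and histone lists (adjusted p = 0.0896, 0.0570, 0.114 and 0.114). It called the SRC-1 linked, integrin, NF-kB, MAPK, TGF-beta, neuronal and mammary lists, which camera did not call. The camera call of the mitochondrial list was also lost with the replicate block (adjusted p = 0.0513). For the histones the length and GC correction is void, since 69.2% have values. Thinned to the smallest depth, the libraries gave 4227 genes.

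With the replicate block 6398 genes were called, 4520 of them among the 4538. The correlations of same-numbered libraries' deviations were 0.24, -0.01, 0.13 and 0.14, and all libraries but the replicates numbered 2 correlated best with the library of their own number, shNT replicate 2 correlating best with shSRC1 replicate 4 and shSRC1 replicate 2 with shNT replicate 1. As 1 of the 4 correlations was not above 0.1, the numbers were not taken to pair the libraries. NCOA3 passed the threshold with the block (adjusted p = 0.0326).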

Other observations

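The lists of NRF2 targets and of cancer-testis genes were written only after the genes with the largest changes were seen, and the genes named here were chosen after their values were seen. The NRF2 test was stated before the values of its list were computed; the SE of its median and its alternative settings were added after.

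Targets of NRF2, the transcription factor of the oxidative stress response, were examined because of AKR1C2 and SLC7A11. Of 24 measured targets, with the AKR1C genes and SLC7A11 left out, 11 fell, none rose and 13 did not pass the test. The ferritin light chain gene FTL fell from 49074 ± 8994 to 21215 ± 1945 normalized reads (n = 4 each, limma adjusted p = 1.47e-05), the drug efflux pump gene ABCC3 from 12283 ± 1596 to 4656 ± 578 and thioredoxin reductase (TXNRD1) from 67335 ± 5935 to 40387 ± 1475. GCLC and GCLM, the subunits of the enzyme that limits glutathione synthesis, fell by 0.41 and 0.27 on the log2 scale. NQO1, a widely used NRF2 target, had a log2 fold change of -0.23 (SE 0.12, limma adjusted p = 0.175), and FTH1 had one of 0.01. FTL has pseudogenes that can share its reads. AKR1C1 and AKR1C3 had log2 fold changes of -2.13 and -2.44, but the reads of these copies can be shared.

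Lower activity of NRF2 may account for the fall of the AKR1C genes and SLC7A11. The prediction was a median below -0.25 over the other targets. It was -0.28, past the bound by less than its bootstrap SE over the genes of 0.11, and over 22 alternatives it ran from -0.38 to -0.25, below the bound in 20 of them but not without shNT replicate 2 (-0.248) or shNT replicate 4 (-0.247), so the test leaves this explanation open. Camera placed this list below the other genes (adjusted p = 1.00e-07), though not with an estimated correlation (adjusted p = 0.147). Both values were adjusted over this list and the cancer-testis list alone. They therefore cannot be set against the adjusted p-values of the lists fixed at the outset. The hypothesis rests on transcripts alone, and AKR1C1, AKR1C2 and AKR1C3 lie in a run of lower genes on chromosome 10 and TXNRD1 in one on chromosome 12. ABCC2, a target that fell with a log2 fold change of -1.69, also lies in a run of lower genes on chromosome 10. TKT, which did not pass the test, lies in the run of higher genes on chromosome 3.

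Cancer-testis genes, which are mostly silent outside the germline and tumours, went both ways. Of 24 measured, 12 fell, 7 rose and 5 did not pass the test. MAGEB1 rose from 56.9 ± 13.5 to 353.8 ± 22.3 normalized reads and MAGEA1 from 2666 ± 246 to 6095 ± 83 (n = 4 each, limma adjusted p = 1.18e-07 and 1.62e-07), while MAGEA12 and MAGEA3 had log2 fold changes of -2.83 and -2.42. Members of the MAGEA and SSX families are near-identical and can share reads, so their separate values are uncertain. SSX2, SSX2B and TDRD1, whose falls prompted the list, are among those that fell, so the list is no independent test of a shift. No explanation was tested.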
